A study of Homo sapiens with 6 samples.

How the data were processed

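RNA was taken from 22Rv1 prostate cancer cells stably transfected with an empty pcDNA3 plasmid after 16 h with DMSO (3 libraries) or 2 µM withaferin A (3 libraries). Per the labels' protocols, total RNA was extracted with an RNeasy kit and libraries followed Illumina protocols. Whether poly(A) selection was used, whether libraries kept strand, and the aligner are not given in the sources used here. Per the submitters' processing notes, HTSeq 0.6.1, DESeq2 (no version given) and edgeR 3.16.5 were among the tools and the genome builds were GRCh37 and hg19. Because strand is not stated, reads from a gene and an antisense or overlapping partner cannot be told apart, and reads of near-identical paralogs and pseudogenes may be divided or lost by the counting.

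The authors deposited whole-number read counts per gene and library for 30509 genes, not normalized. They also deposited FPKM values for 48162 genes. The 17653 genes found only in the FPKM table were 0 in all 6 libraries. The deposited FPKM values equalled the count divided by gene length and by the total count of the library, to a relative difference of at most 4.95e-12. The authors' deposited comparison table further holds gene lengths, a mean signal per group, log2 fold changes and p-values. The mean signal equalled the mean of counts divided by median-of-ratios size factors, to a relative difference of at most 4.82e-15, and is not divided by gene length. No row lacked a gene name. Coordinates are those of the authors' table, in GRCh37/hg19.

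Groups came from the sample titles. Total counts per library ran from 22304136 to 25704328, so that a floor of 3 counts corresponds to 0.117 to 0.135 CPM. Fewer than 10 counts over all 6 libraries were found for 8235 genes. Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom of 2.72 to 6.77 over genes with at least 20 counts in the pair, and no pair of columns was identical. Log CPM values correlated at 0.9905 or more within groups and at 0.883 or less between groups, across genes, which are not independent replicates.

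The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on the deposited counts with TMM scaling, genes filtered by filterByExpr (minimum count 10; 17185 kept) and Benjamini-Hochberg adjustment at 0.05, two-sided. Standard errors of log2 fold changes were taken as the absolute value divided by the square root of F. A fold printed for a gene is that of this fit. Where a group had no read, a bound was computed against 3 counts over the group, and where it had 1 to 3 reads a ratio was given with an exact 95% binomial interval.

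Gene lists (33 lists with 630 entries) were fixed before the data were examined. Of the entries 624 matched a gene of the count table, 28 of them through an older symbol, and 577 were tested. Lists with at least 3 tested members (30) were tested with camera on log CPM (limma 3.58.1, prior count 2, preset correlation 0.01), and again with an estimated correlation and with fry. With an estimated correlation camera takes its degrees of freedom from the 6 libraries and not from the genes, so it has little power here. The named genes follow a rule fixed at the same time. They are the 6 most raised and 6 most lowered protein-coding genes by fitted log2 change with an adjusted p under 0.05, at least 1 FPKM in the higher group and no overlap between groups, the 2 called members of each list with the largest absolute change (or the member with the highest level where none was called), and a few genes fixed in any case, among them MYC, VIM, KLK3, HSP90AA1 and FASN. Results for some genes that meet the rule are not reported here.

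The fitting steps were tested on simulated data, with counts drawn from the real means and library sizes. In the simulated comparison of withaferin A with vehicle, 200 of 16813 genes were changed. The test recovered 60% of those changed 1.25-fold and 95% of those changed 2-fold, and 3 unchanged genes were called (1.90% of calls). The list test called the set of changed genes and 0 of 30 random sets. These rates hold for few changed genes, in equal numbers up and down, with counts drawn independently for each gene. In the data 79.8% of tested genes were called and members of some lists varied together, so the rates need not carry over.

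Alternatives were DESeq2 1.42.0, limma on log2(FPKM + 1) with and without quantile normalization and on log2(FPKM + 0.1) (genes of at least 0.5 FPKM in a group), median-of-ratios scaling, no filter, a filter of 1 FPKM, the replicate number as a block, and leaving out each library. Scaling by total counts and a fit without the 13 mitochondrial genes were added after the data were seen. Figures were drawn with matplotlib.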

Results

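The transcriptome of 22Rv1 cells, an established human prostate cancer line, was measured by RNA sequencing after exposure to withaferin A, a plant steroidal lactone. The cells carried a stably transfected empty pcDNA3 plasmid. The design holds 3 libraries from cells given vehicle (DMSO at 0.01%) and 3 from cells given 2 µM withaferin A, all collected after 16 h. The deposited table gave counts for 30509 genes. Total counts in the vehicle libraries were 22854418, 22821866 and 25704328, and in the withaferin A libraries 22304136, 23480884 and 23372965. The dishes were plated in triplicate, and no source used here states that replicates came from separate days or passages, so p-values measure the spread between these samples, which may be technical. No batch label was given, so a batch that followed treatment could not be told apart from it.

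The comparison asked which transcripts differ between withaferin A and vehicle. Most of the measured transcriptome did. On the gene lists fixed beforehand, 22 of 22 heat shock chaperones, 24 of 27 NRF2 target genes and 31 of 32 proteasome subunits rose. In turn 29 of 29 replication genes, 31 of 31 mitosis genes, 23 of 24 ribosome biogenesis genes and 32 of 37 nuclear-encoded respiratory chain genes fell. Each of these 7 lists passed by camera with a preset correlation and none did with an estimated correlation (adjusted p = 0.194 to 0.294 with an estimated correlation). Among 17185 genes tested, 6859 rose and 6847 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 3 per group), which is 79.8% of those tested. Rises and falls are relative to the other genes, since TMM scaling centres the changes (median log2 change 0.01). The near-equal split depends on this scaling, and with total-count scaling 7349 rose and 6283 fell. A change in the amount of RNA per cell could not be seen. At least 2-fold changes were found in 6854 genes, of which 3508 rose and 3346 fell. Changes of 8-fold or more were found in 648 raised and 300 lowered genes. The values of both groups did not overlap in 13862 tested genes (80.7%), where chance gives 10%. The common biological coefficient of variation was 0.0528, and the first principal component, which separated the groups, held 91.1% of the variance.

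**Figure D1:**
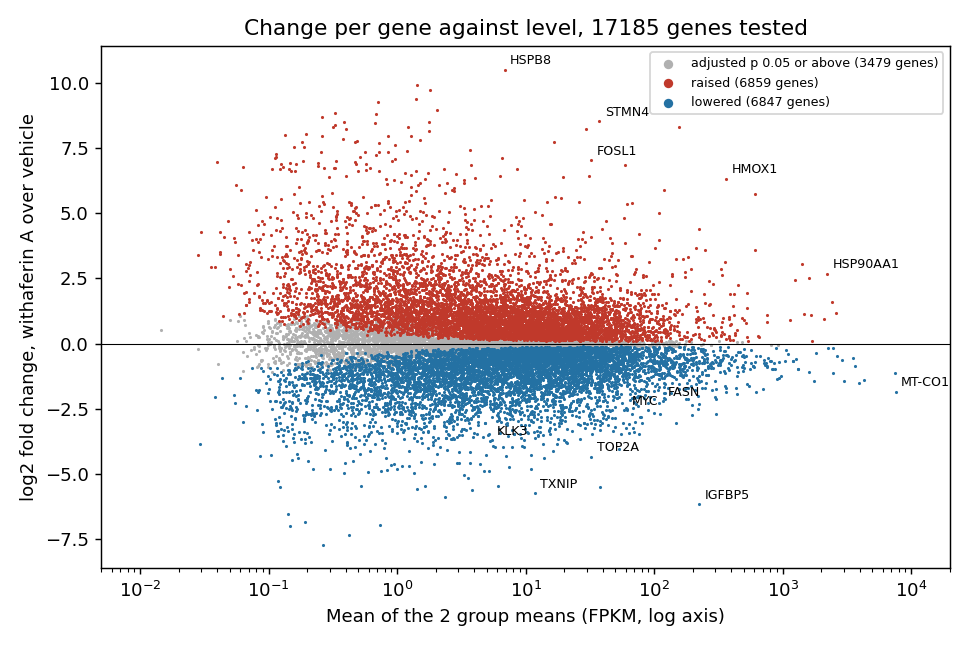
Each point is 1 of the 17185 genes tested. The x axis is the mean of both group means in FPKM on a log axis and the y axis is the log2 fold change of withaferin A over vehicle. Red points are the 6859 raised genes, blue points the 6847 lowered genes and grey points the 3479 genes with an edgeR adjusted p of 0.05 or above.

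The 6 protein-coding genes with the highest fitted log2 changes under the naming rule included 5 with 0 or 1 read in vehicle, whose fitted values depend on the prior count and do not rank them against other genes. HSPB8, a small heat shock protein (chromosome 12, 119616447 to 119658936 in GRCh37), had 1 read in the vehicle libraries together and 2044 in the withaferin A libraries, a ratio of 1986 (95% counting interval 356 to 78484). PCYT1B, an enzyme of phosphatidylcholine synthesis, also had 1 vehicle read, against 491 reads after treatment, a ratio of 477 (85.2 to 18882). SSX1, a cancer-testis antigen, RAET1L, a ligand of the receptor NKG2D, and P2RY6, a nucleotide receptor, had no vehicle read. Against a floor of 3 counts over the vehicle group they were at least 105-fold, 81.0-fold and 75.8-fold higher. SSX1 belongs to a family of near-identical genes that can share reads. STMN4, a stathmin that binds tubulin, rose from 0.189 ± 0.0999 to 74.7 ± 3.01 FPKM (SD, n = 3), a log2 change of 8.52 ± 0.12 (SE; edgeR adjusted p = 4.08e-27). Such floors and intervals cover counting error only.

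Among protein-coding genes the deepest falls included IGFBP5, an insulin-like growth factor binding protein (chromosome 2, 217536828 to 217560248 in GRCh37). Its mean dropped from 444 ± 31.0 to 6.58 ± 1.33 FPKM, a log2 change of -6.16 ± 0.09 (SE; edgeR adjusted p = 4.08e-27). TERT, the catalytic subunit of telomerase, went from 4.67 ± 0.553 to 0.0825 ± 0.0207 FPKM. TXNIP, which binds thioredoxin, went from 23.2 ± 1.15 to 0.465 ± 0.0752 FPKM, a 52.8-fold fall. APLN, the peptide hormone apelin, fell from 74.0 ± 2.65 to 1.75 ± 0.0907 FPKM. PRIMA1, the membrane anchor of acetylcholinesterase, had 273 vehicle reads and 6 after treatment. A gene known only by the clone-based name RP11-664D7.4 had 168 vehicle reads and 1 read after treatment, a ratio of 0.00578 (0.000146 to 0.0327). All of these 12 genes passed the edgeR test, with adjusted p-values no higher than 1.09e-10.

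All 22 chaperones on the fixed heat shock list rose, also when adjusted over the list alone, with a median log2 change of 2.18 (camera adjusted p = 8.77e-11; adjusted p = 0.194 with an estimated correlation). HSP90AA1, the stress-inducible HSP90, was abundant in vehicle at 569 ± 12.6 FPKM and reached 3876 ± 69.1 FPKM, a 6.42-fold rise (edgeR adjusted p = 1.63e-26). CRYAB, a small chaperone, rose from 0.219 ± 0.162 to 10.6 ± 0.0326 FPKM. HSPA1A and HSPA1B are near-identical copies, so reads cannot be assigned to either with certainty.

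The antioxidant genes controlled by the transcription factor NRF2 moved the same way. Of 27 tested, 24 rose and 3 fell, the same counts as when adjusted over the list alone, with a median log2 change of 2.27 (camera adjusted p = 1.48e-08; adjusted p = 0.208 with an estimated correlation). HMOX1, heme oxygenase 1 (chromosome 22, 35776354 to 35790207 in GRCh37), rose 79.9-fold, from 8.49 ± 1.39 to 719 ± 28.5 FPKM (edgeR adjusted p = 2.02e-28). AKR1B10, an aldo-keto reductase with close paralogs that can share reads, went from 4 vehicle reads to 360. The 3 that fell were PGD and TKT of the pentose phosphate pathway and TXN, with log2 changes of -0.68, -0.38 and -0.12. Members named to account for small counts, here and below, were chosen after their values were seen.

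Proteasome subunits rose together, 31 of 32 of them, with 1 lowered, also when adjusted over the list alone. Their median log2 change was 1.06 (camera adjusted p = 3.38e-10; adjusted p = 0.294 with an estimated correlation). PSMC4, an ATPase of the regulatory particle, rose from 97.7 ± 1.50 to 393 ± 9.50 FPKM, and PSMD12 rose from 26.1 ± 1.16 to 105 ± 1.27 FPKM. The lowered subunit on the list was PSMD5, an assembly chaperone, with a log2 change of -0.81. On the autophagy and lysosome list 15 of 20 members rose and none fell, likewise when adjusted over the list alone, with a median of 0.65 (camera adjusted p = 5.25e-05; adjusted p = 0.194 with an estimated correlation). SQSTM1, an autophagy receptor, rose 12.2-fold to 465 ± 10.8 FPKM. GABARAPL1, an ATG8 family protein, rose 25.9-fold to 81.4 ± 3.54 FPKM. The 5 that did not pass were TFEB (-0.13), ATG7 (-0.09), GABARAPL2 (-0.06), BECN1 (0.15) and UVRAG (0.20), given as log2 changes.

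Targets of ATF4 in the integrated stress response rose in 21 of 28 cases and fell in 6, the same counts as when adjusted over the list alone. The median log2 change was 0.88 (camera adjusted p = 6.37e-05; adjusted p = 0.283 with an estimated correlation). CTH, which makes cysteine from cystathionine, rose 43.0-fold, and ATF3, a stress-induced transcription factor, rose from 13.9 ± 0.591 to 189 ± 2.70 FPKM. VLDLR did not pass, with a log2 change of 0.04. Endoplasmic reticulum chaperone genes divided instead. There 11 rose and 8 fell among 20, also when adjusted over the list alone, and the list did not pass (median 0.23, camera adjusted p = 0.447). HSPA5, the main chaperone of that compartment, rose 4.76-fold to 748 ± 44.6 FPKM and DNAJB9, its cochaperone, rose 4.72-fold. HYOU1 did not pass, with a log2 change below 0.01 in size.

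Immediate early genes rose in 14 of 16 cases, also when adjusted over the list alone, with a median log2 change of 1.94 (camera adjusted p = 4.29e-05; adjusted p = 0.283 with an estimated correlation). FOSL1, a subunit of the AP-1 transcription factor, rose from 0.460 ± 0.0804 to 64.6 ± 3.22 FPKM, and EGR3 rose 30.3-fold. MYC was the lowered member, and DUSP1 did not pass (0.05). The hypoxia-inducible list had 9 raised, 2 lowered and 2 not past the threshold, equally when adjusted over the list alone, and a median of 1.34 (camera adjusted p = 0.00588; adjusted p = 0.267 with an estimated correlation). ADM, the vasodilator adrenomedullin, rose 41.3-fold to 121 ± 7.58 FPKM and P4HA1, a collagen prolyl hydroxylase, rose 5.92-fold. PDK1 and LOX were the lowered members (log2 changes of -1.76 and -0.91), and BNIP3 (log2 change under 0.01) and PFKFB3 (0.10) did not pass.

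Cell cycle genes fell throughout the lists. All 29 genes of S phase and DNA replication and all 31 of G2/M and mitosis fell, also when adjusted over the list alone. The medians were -2.18 for replication (camera adjusted p = 5.48e-14; adjusted p = 0.194 with an estimated correlation) and -2.81 for mitosis (camera adjusted p = 1.48e-14; adjusted p = 0.294 with an estimated correlation). TOP2A, topoisomerase II alpha, fell from 61.9 ± 4.93 to 3.25 ± 0.729 FPKM, and AURKB, a mitotic kinase, fell 16.5-fold to 6.51 ± 0.742 FPKM. UHRF1, which recruits maintenance DNA methylation, fell 17.4-fold, and RRM2, a subunit of ribonucleotide reductase, fell 8.73-fold. On the list of p53 targets 14 of 22 rose and 3 fell, also when adjusted over the list alone, with a median of 0.70 (camera adjusted p = 0.00535; adjusted p = 0.194 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 75.7 ± 2.66 to 589 ± 0.614 FPKM (edgeR adjusted p = 2.41e-26). GDF15, a secreted stress cytokine, rose 6.13-fold. The lowered members DDB2 and BTG2 had log2 changes of -1.23 and -0.73, and FDXR had -0.64. The 5 not past the threshold were SPATA18 (-0.06), CCNG1 (-0.03), RRM2B (-0.01), XPC (0.08) and TP53I3 (0.35).

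MYC, a transcription factor that drives growth, fell from 103 ± 1.37 to 18.8 ± 0.666 FPKM, a log2 change of -2.54 ± 0.05 (SE; edgeR adjusted p = 1.79e-24). On the list of MYC and ribosome biogenesis genes 23 of 24 fell, also when adjusted over the list alone, with a median of -1.44 (camera adjusted p = 3.59e-09; adjusted p = 0.194 with an estimated correlation). BOP1, which processes ribosomal RNA, fell 7.89-fold, and RRP12 was the raised member (0.41). All 43 cytosolic ribosomal protein genes tested fell, likewise when adjusted over the list alone, by a smaller amount (median -0.74, camera adjusted p = 4.27e-12; adjusted p = 0.345 with an estimated correlation). RPL7A fell from 1288 ± 65.1 to 532 ± 6.72 FPKM and RPS23 fell from 14.0 ± 0.507 to 5.97 ± 0.461 FPKM. Ribosomal protein genes have many processed pseudogenes that can share reads, so single values are uncertain.

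KLK3, which encodes prostate-specific antigen and is induced by androgen, fell from 10.1 ± 0.504 to 0.821 ± 0.206 FPKM (edgeR adjusted p = 3.97e-19). Of 24 androgen-induced genes tested 17 fell, 6 rose and 1 did not pass, equally when adjusted over the list alone. The median log2 change was -1.04 (camera adjusted p = 0.0316; adjusted p = 0.335 with an estimated correlation). C1orf116 moved against the majority and rose from 0.770 ± 0.118 to 16.2 ± 1.26 FPKM. HOMER2 did not pass (0.15).

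Respiratory chain transcripts fell in both genomes. On the nuclear-encoded list 32 of 37 fell, 1 rose and 4 did not pass, also when adjusted over the list alone, with a median of -0.74 (camera adjusted p = 9.49e-09; adjusted p = 0.294 with an estimated correlation). SDHA, a subunit of complex II that has pseudogene copies, fell 3.23-fold and ATP5G3, a subunit of ATP synthase, fell 3.21-fold. NDUFA4 rose (0.19), and NDUFA2 (-0.25), SDHC (-0.04), UQCRQ (0.05) and NDUFV2 (0.14) did not pass. Of 13 mitochondrially encoded messenger RNAs 12 fell, also when adjusted over the list alone, with a median of -0.98 (camera adjusted p = 0.000128; adjusted p = 0.361 with an estimated correlation). MT-CO1 dropped from 11685 ± 674 to 3455 ± 57.1 FPKM and MT-ATP6 from 5774 ± 292 to 2133 ± 118 FPKM. MT-ATP8 did not pass (-0.02). Mitochondrial genes held 5.60 ± 0.323% of counts in vehicle and 2.63 ± 0.125% after treatment (n = 3 per group, two-sided exact permutation p = 0.1, the smallest that 3 against 3 samples allow).

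Lipid and sugar metabolism lists divided between raised and lowered members, and none of the 4 passed. FASN, fatty acid synthase, fell 4.60-fold, from 190 ± 8.75 to 43.8 ± 2.10 FPKM (edgeR adjusted p = 4.9e-24). ACLY, which makes cytosolic acetyl-CoA, fell 6.61-fold, from 341 ± 14.6 to 54.8 ± 1.96 FPKM. ACSL4, an acyl-CoA synthetase at a low level, rose 7.47-fold, from 0.154 ± 0.0315 to 1.23 ± 0.0541 FPKM. Of 18 fatty acid synthesis genes 8 rose and 10 fell (median -0.14, camera adjusted p = 0.740). In fatty acid oxidation 4 rose and 10 fell among 17 (median -0.41, camera adjusted p = 0.0885), including HADH and ECI1, which fell 3.21-fold and 3.19-fold. ECI2 (-0.16), HADHA (-0.09) and CPT2 (0.10) did not pass, and the raised members included SLC25A20, ACADVL and HADHB. This list passed in a fit with no filter on low counts (camera adjusted p = 0.00964; 0.0654 to 0.335 over the other camera alternatives). Cholesterol synthesis and uptake had 14 raised and 7 lowered among 23 (median 0.27, camera adjusted p = 0.135), with STARD4, a sterol carrier, 8.65-fold and HMGCS1, an early enzyme of the pathway, 4.33-fold higher. NSDHL (-0.05) was among those that did not pass. In glycolysis 8 rose and 9 fell among 19 (median -0.06, camera adjusted p = 0.641), PFKL being 4.42-fold lower and the glucose transporter SLC2A1 4.17-fold higher. TPI1 (-0.06) and HK1 (-0.05) did not pass. For these 4 lists the counts were the same when adjusted over the list alone.

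**Figure D2:**
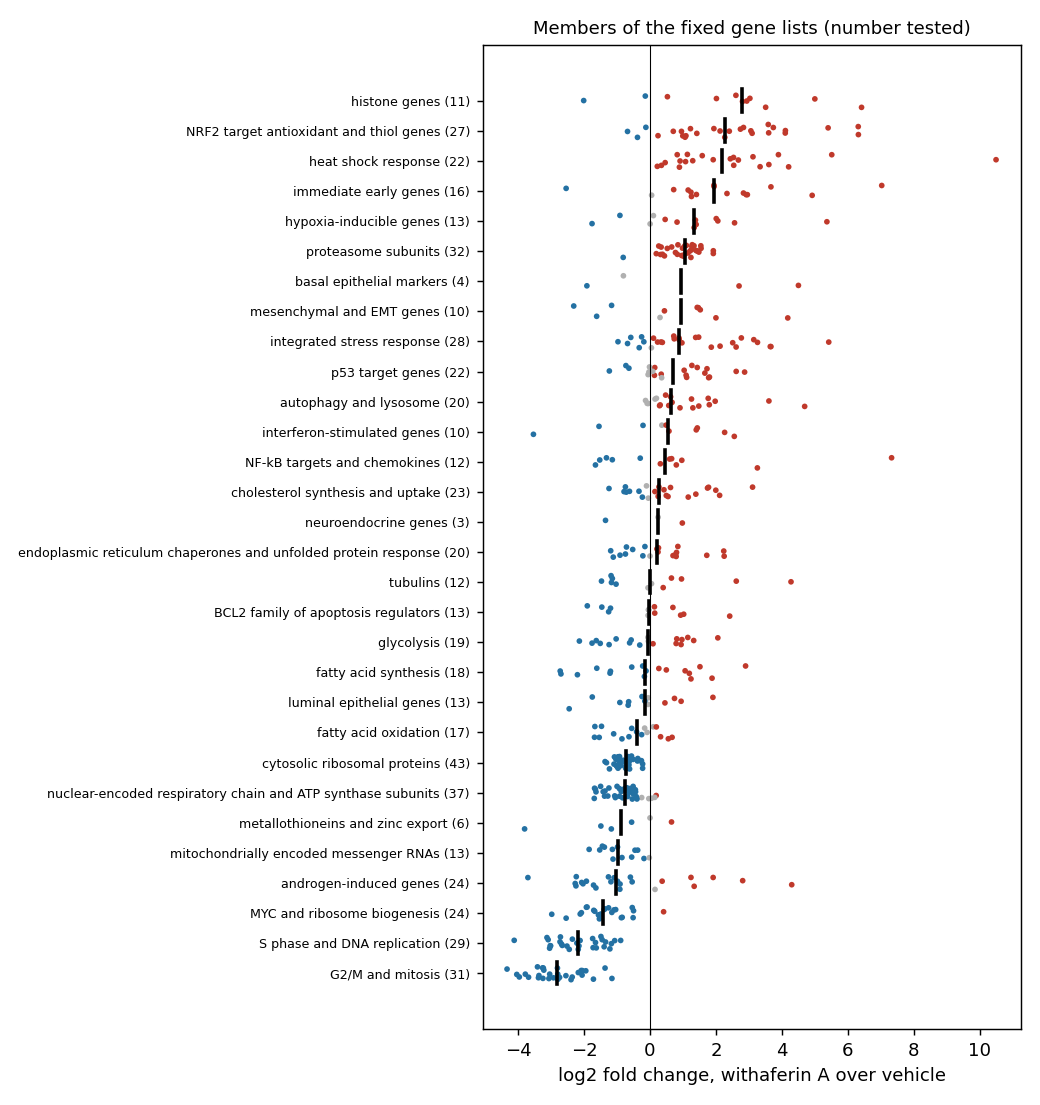
Each point is a tested member of a fixed gene list and each black bar the median of its list, with the number of members tested in brackets. The x axis is the log2 fold change of withaferin A over vehicle, and red, blue and grey mark raised members, lowered members and members not past the edgeR threshold. The medians run from -2.81 for G2/M and mitosis to 2.81 for histone genes.

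Histone genes were raised in 9 of 11 cases, also when adjusted over the list alone, with a median of 2.81 (camera adjusted p = 0.00417; adjusted p = 0.194 with an estimated correlation). HIST1H4H rose from 0.679 ± 0.153 to 62.1 ± 1.46 FPKM and HIST2H2BE from 6.25 ± 0.470 to 213 ± 8.70 FPKM. H1F0 and H2AFZ, both outside the main histone clusters, were the lowered members (-2.01 and -0.14). Histone genes are near-identical in part and can share reads.

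The remaining lists did not pass, and their members went both ways. In the BCL2 family 6 rose and 4 fell among 13, with MCL1, an antiapoptotic member, 5.35-fold higher and BCL2, another, 3.74-fold lower. MCL1 went from 79.6 ± 3.60 to 453 ± 18.2 FPKM, whereas BCL2 was low in both groups (0.621 ± 0.248 and 0.177 ± 0.0526 FPKM). BID, BMF and BAD also fell, and BIK (-0.06), BCL2L1 (-0.05) and PMAIP1 (-0.04) did not pass. The list's camera adjusted p was 0.762, its median -0.04 and its mean -0.05, opposite in sign to the direction of the test. NF-kB targets had 7 raised and 5 lowered among 12 tested of 21 on the list (camera adjusted p = 0.727). Their median of 0.46 held with IL8 at its bound, and the lowered members were CSF1, BCL3, TRAF1, NFKBIA and NFKB1. RELB, a subunit of the factor, rose 9.57-fold, and IL8, a chemokine, had no vehicle read and was at least 19.8-fold higher against the floor of 3 counts over the vehicle group. Interferon-stimulated genes had 6 raised, or 7 when adjusted over the list alone, and 3 lowered among 10 tested of 16 on the list (median 0.53, camera adjusted p = 0.248). OAS3 fell from 106 reads to 9, IFI6 rose 5.89-fold, IFI27 and IRF7 were the other lowered members, and MX1 (0.36) did not pass. On the list of metallothioneins and zinc export 4 of 6 tested members fell and 1 rose, with 9 on the list (median -0.86, camera adjusted p = 0.248). MT1F was 14.0-fold and MT1G 2.81-fold lower, MT1E and MT2A fell too, SLC30A1, a zinc exporter, rose, and MT1X (log2 change under 0.01) did not pass. Tubulin genes had 5 raised and 5 lowered among 12 (camera adjusted p = 0.790), and the median of -0.01 lay opposite to the mean of 0.24 and to the direction of the test. TUBA4A rose 19.4-fold and TUBB2A 6.14-fold, also raised were TUBB6, TUBA1A and TUBA1C, the lowered members were TUBA1B, TUBG1, TUBB2B, TUBB and TUBB3, and TUBB4A (-0.06) and TUBB4B (0.05) did not pass. Metallothionein and tubulin genes have close paralogs that can share reads. Apart from the interferon list, counts in these lists were the same when adjusted over the list alone.

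Lineage markers gave no uniform picture. VIM, the mesenchymal filament vimentin, measured 1.11 ± 0.0238 FPKM in vehicle and 1.46 ± 0.349 after treatment and did not pass (log2 change 0.30 ± 0.20 SE, edgeR adjusted p = 0.166), though it passed without withaferin A replicate 2 (0.50, edgeR adjusted p = 0.0300; 0.0300 to 0.598 over all alternatives). Mesenchymal genes had 6 raised and 3 lowered among 10 tested of 14 on the list (median 0.94, camera adjusted p = 0.288). ZEB1, a repressor of epithelial genes, was 18.1-fold higher and MMP14, a matrix protease, 4.97-fold lower. FN1 and MMP9 also fell. Luminal epithelial genes had 4 raised and 7 lowered among 13 (median -0.16, camera adjusted p = 0.455). HOXB13, a prostate homeobox factor, was 5.47-fold lower and the keratin KRT18 3.76-fold higher, while CDH1 (-0.06) and KRT19 (-0.05) did not pass and CLDN4, OCLN and KRT8 were the other raised members. Of 4 basal markers tested, from 6 on the list, LAMB3 and KRT15 rose, 22.7-fold and 6.51-fold, ITGB4 fell and KRT5 (-0.81) did not pass (list median 0.95, camera adjusted p = 0.447). Only 3 of the 10 neuroendocrine genes on the list were tested. Of these SCG2 rose 1.97-fold, SYP (0.25) did not pass and SCG3 fell from 62 reads to 25 (edgeR adjusted p = 0.0108). SCG3 did not pass without vehicle replicate 2 (log2 change -0.78, edgeR adjusted p = 0.183; 0.00454 to 0.183 over the 12 alternatives that tested it), without withaferin A replicate 1 or with DESeq2. The neuroendocrine median was 0.25 and the mean -0.04 (camera adjusted p = 0.740). In these 4 lists the counts were the same when adjusted over the list alone.

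Markers of other cell types were low. The fibroblast, leukocyte and endothelial lists had fewer than 3 tested members each and were not tested as lists. COL1A1, a collagen chain, rose from 0.639 ± 0.0673 to 3.34 ± 0.194 FPKM. COL1A2 rose from 0.0409 ± 0.0599 to 0.361 ± 0.0890 FPKM, and 15 of its 17 vehicle reads came from vehicle replicate 2, without which its log2 change was 5.45 in place of 3.07. CD14 rose from 22 reads to 91 and VWF from 5 to 86.

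**Figure D3:**
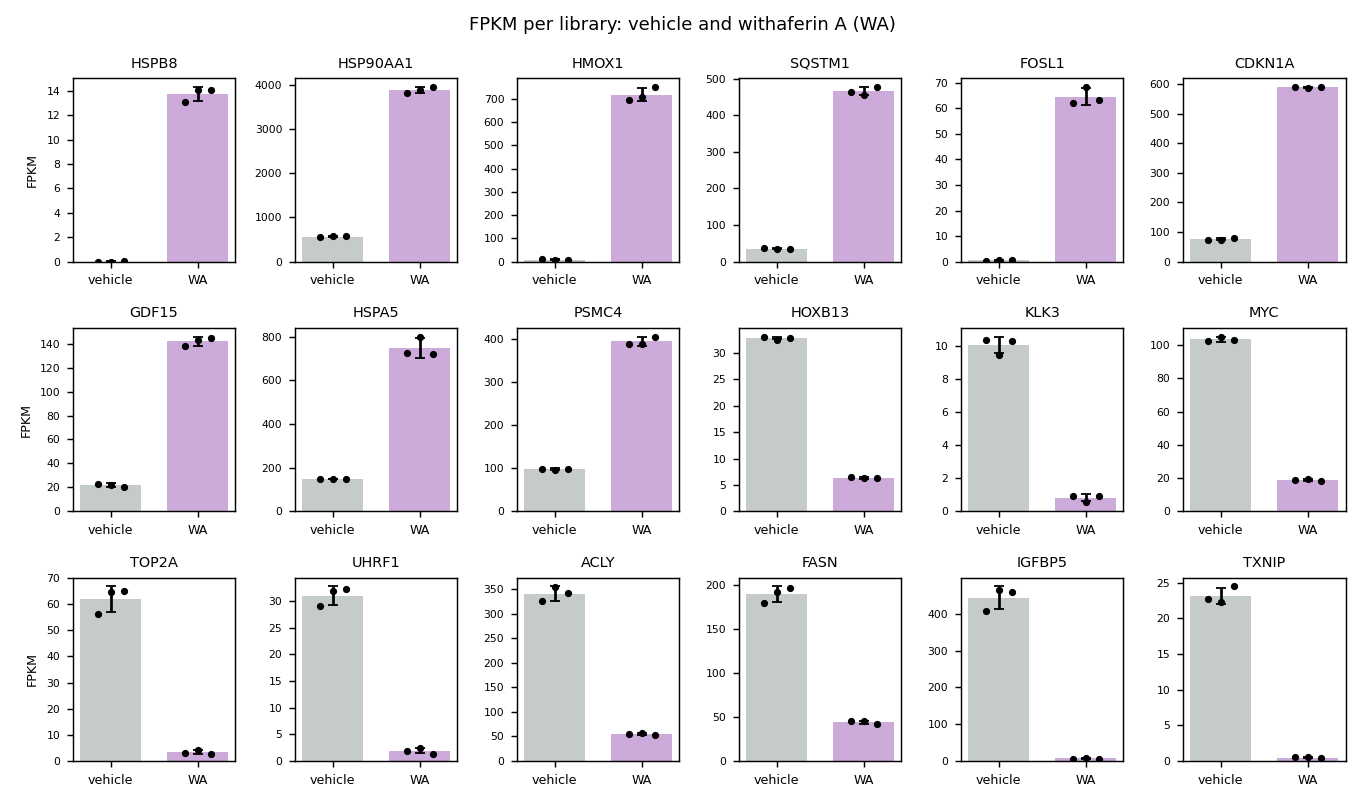
Bars show the mean FPKM of 3 vehicle and 3 withaferin A (WA) libraries for 18 genes, error bars the SD and points the libraries, on linear axes that start at 0. In every panel the points of both groups are separate, from HSP90AA1 at 569 against 3876 FPKM to IGFBP5 at 444 against 6.58 FPKM.

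With the preset inter-gene correlation of 0.01, 9 of the 30 lists tested rose and 7 fell by camera, and with an estimated correlation no list passed (adjusted p = 0.194 to 0.899). The autophagy, p53 and histone lists lost their calls though their estimated correlations (-0.042, -0.015 and 0.003) lay below the preset one. Their unadjusted camera p rose from 1.75e-05 to 0.00941, from 0.00250 to 0.0292 and from 0.00181 to 0.0320. A higher correlation cannot be the reason there, so failing this form does not by itself argue against a list. In contrast fry, which asks whether a list moves on balance in a direction without reference to other genes, called all 30. The authors' deposited table gave 13600 genes an adjusted p under 0.05, of which 6993 rose and 6607 fell. Of the calls made here 12715 (92.8%) were also called in the authors' deposited table, all in the same direction.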

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

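The count of changed genes was 13706 of 17185 tested. It ran from 12174 of 14562 (filter of 1 FPKM) to 14823 of 30509 (no filter) over the settings chosen beforehand that kept all libraries. The 2 ends thus differ in the number of genes tested, and the share called was lower with no filter. When each library was left out the count was 13351 to 13810. The scaling by total counts (13632) and the fit without mitochondrial genes (13705) were chosen after seeing the data, the former with 53.9% of calls raised. The number changed at least 2-fold fell from 6854 to 4053 with limma on log2(FPKM + 1) and to 4015 with quantile normalization added. The pseudocount of 1 shrinks changes of low genes, and with 0.1 the number was 6419. Of the 30 gene lists camera called 16, and 0 with an estimated correlation, while fry, which does not compare a list with other genes, called 30. At these depths a count of 0 in a library allows up to 0.117 to 0.135 CPM. Over 1258 values of named genes under alternatives 1251 kept their direction and side of the threshold, 6 lost the call, 1 gained it and 0 reversed. Among the 6 was SCG3 with DESeq2 (adjusted p = 0.0529) and without vehicle replicate 2 (0.183) or withaferin A replicate 1 (0.0533). SCG3 had 15, 34 and 13 reads in the vehicle libraries, and the causes were not tested. The gain was VIM without withaferin A replicate 2. Most named genes were chosen for large changes in these same counts, so their stability says little about the other calls.

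Replicate numbers were shared between groups, but same-numbered libraries did not deviate together (correlations across genes of -0.01, 0.03 and -0.02), so they were not treated as paired, and not every library correlated best with its own number. With the replicate block 13503 genes changed, 6754 raised and 6749 lowered, 6823 of them at least 2-fold, and 16 lists were called.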

Other observations

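The patterns below, including the thresholds for genes near 0, the histone genes by symbol and the families of shared symbol stems, were noticed in the data. The test of other abundant transcripts of fibroblasts, leukocytes and endothelium, the test on the opposite strand, the test of a common scale factor and the permutation test between histone genes and their neighbours were chosen only after the result was seen.

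Families of genes were called only with the preset correlation. Among 239 families of protein-coding genes that share a symbol stem and have at least 8 tested members, 5 rose and 6 fell by camera with the preset correlation, and 0 passed with an estimated correlation (lowest adjusted p = 0.809 with an estimated correlation). Even the RPL genes, with 48 of 49 lowered, had a camera adjusted p of 0.809 in that form. It gave most families that same value, so it did not separate them and does not argue against their changes. The ZNF genes, many of them transcription factors with zinc fingers, had 312 raised and 82 lowered among 457 (median log2 change 0.63, camera adjusted p = 5.32e-06; adjusted p = 0.809 with an estimated correlation). The HSPA genes, the HSP70 family, had 12 raised and 1 lowered among 13 (median 1.49, camera adjusted p = 0.000568; adjusted p = 0.809 with an estimated correlation). Many zinc finger genes have close paralogs that can share reads. The NUP genes, most of which encode nuclear pore proteins, had 18 lowered and 2 raised among 21 (median -0.65, camera adjusted p = 0.00236; adjusted p = 0.809 with an estimated correlation). Protein-coding genes in the shortest of 10 length classes had a median log2 change of -0.25 and those in the longest class 0.18. More genes were detected after withaferin A, 24901 ± 112 against 23001 ± 132 (n = 3 per group, two-sided exact permutation p = 0.1, the smallest possible).

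Genes near 0 in vehicle rose more often than the reverse. From under 0.1 to at least 1 FPKM 125 genes rose, 62 of them protein-coding and 19 with no vehicle read, and 22 fell the other way. Members named here after their values were seen were ABCB1, a drug efflux pump, and MMP1, a collagenase, which rose by log2 changes of 7.42 and 6.50. Run-on from an active gene that ends within 20 kb upstream on the same strand was argued against as a common cause. Such a neighbour was found for 6 of the 125 and for 462 of 7967 genes near 0 in both groups (odds ratio 0.819, 95% interval 0.293 to 1.85, Fisher's exact test). For upstream genes on the opposite strand the numbers were 13 and 418 (odds ratio 2.10, 1.07 to 3.77, adjusted p = 0.0473 by Fisher's exact test over both strands). The interval for the same strand still allows some excess. Active genes that overlap the risen gene, lie farther away or converge on it were not counted, so run-on from those stays open. Cells of another type were first tested by whether every marker stayed under 1 FPKM, which left the question open because COL1A1 was at 3.12 FPKM or more in each treated library, yet was present in vehicle too. Their other abundant transcripts, COL1A2, COL3A1, DCN, LUM, PTPRC, LYZ and VWF, reached at most 0.462 FPKM in a treated library. The rule first written for this second test, that all 7 stay under 1 FPKM, was met, but it left out COL1A1 and set no level expected from a share of such cells. It was changed after its outcome was known to require also that no marker on the lists rose. COL1A2 and VWF rose, so the changed rule was not met. It could hardly have been met where 79.8% of tested genes were called, and so decides nothing. COL3A1, DCN, LUM and THY1 had lower means than in vehicle, with at most 0.0149 FPKM in a treated library. PDGFRB and POSTN had higher means (0.145 and 0.0220 FPKM after treatment). KDR and TEK reached at most 0.0188 FPKM. At such levels other cells stay open beside an effect of withaferin A.

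Ribosomal protein genes fell by a median log2 change of -0.74. A fit without mitochondrial genes and the 100 most abundant other genes gave -0.73, but it shifted the other genes by a median below 0.01 and so decides nothing on library composition. One scale factor common to all genes was argued against as the whole cause, since it would leave the list's difference of -0.49 from lists matched on length and level, whose 95% range it lay below. Deposited gene length with high abundance was argued against as the whole cause, because 0.06% of 10000 lists matched on both had a median as low. Matched lists had a median of -0.25 (95% of them -0.59 to 0.06), so that part of the fall may go with that class of genes or with composition. The deposited gene length (median 2008 bases for the list, 3437 for RPS23) need not be the length of the expressed transcript. The matching therefore cannot argue against short transcripts as a cause. The matched genes were drawn independently, whereas the ribosomal protein genes varied together (estimated correlation 0.71). The 0.06% and the 95% range are thus narrower than for lists of genes that move together, and do not measure chance for such a list. How closely the matched genes reached the level of these abundant genes was not checked. A response to withaferin A remains a hypothesis.

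Histone genes rose while replication genes fell. By symbol 34 of 41 rose and 2 fell (median 2.61). The 12 protein-coding neighbours between the histone genes on chromosome 6 (26020718 to 27861669 in GRCh37) had a median of 0.81, between the bounds set beforehand. A region-wide rise could thus account for part of the change there. The 32 histone genes there lay 1.92 higher in median (permutation of genes, p = 0.00093). That permutation took genes as independent, which near-identical histone genes that can share reads may not be. Its p may therefore be too small, and it measures no spread between libraries. More RNA without a poly(A) tail in the treated libraries met its test with a median of 1.08, but that rests on 3 RNAs, RN7SL1 (0.29), SNORD3A (1.08) and SCARNA2 (2.34), of which the abundant RN7SL1 moved least. Of the 9 histone genes elsewhere 5 rose and 2 fell, which a rise of that region would not explain. More RNA without a poly(A) tail stays open as a technical explanation. A rise of the region stays open for the genes on chromosome 6 and would itself be compatible with an effect of withaferin A. Reads shared between histone copies were not tested.

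With 10 splits of the 6 libraries into 3 and 3, the number of splits is too few for a share under 0.05. The real split called 13706 genes by edgeR and was the 1 split of the 10 to call as many. The highest of the other splits called 0 genes (24 to 41 genes at an unadjusted p under 0.05 in the others). Each of those splits mixed vehicle and withaferin A libraries in both groups, so the treatment difference entered the spread within groups. Few calls had to follow there, and the 0 gives no rate of false calls.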
